A study of Mus musculus with 18 samples.

How the data were processed

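RNA was sequenced from 18 cultures of mouse mammary epithelial organoids, 3 biological replicates in each of 6 groups made by 2 genotypes and 3 media. Per the labels, the organoids came from mammary glands of 6 to 7 week old C57BL/6 mice, either wild type (WT) or lacking RasGRP1 (KO). They were embedded in matrigel, a basement membrane gel, in DMEM/F12 with insulin, transferrin and selenium. They were treated for 5 days with EGF at 2.5 nM (EGF medium), with NGS-Wnt at 0.1 nM plus Rspo2 at 8.3 nM (WR medium), or with all of these factors (EGF-WR medium). NGS-Wnt is a surrogate Wnt ligand and Rspo2 (R-spondin 2) raises the response of cells to Wnt. Per the labels, organoids were dissociated with TrypLE, RNA was purified on columns, libraries were made from 100 ng of total RNA with a NuGEN kit, and single-end reads of 50 bases were made on an Illumina instrument. The labels give each sample a batch, which equals its replicate number, so that each of the 3 batches holds 1 library of every group.

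The authors deposited a table of read counts per Ensembl gene. Per the labels, STAR, DESeq2 and the GRCm38 genome were used; the versions, the annotation release, the strand setting of the counting and which tool counted the reads are not given in the sources used here. The table holds 55536 genes and whole numbers only. The deposited second table gives, per the file headers, each library's normalized signal, which is its count divided by 1 size factor per library within rounding. The same table holds variance-stabilized values on a log2 scale, made by the authors and not used here in any test. Per the file headers it also holds, for each comparison, the authors' log2 fold change, its fold as a ratio, a p-value and an adjusted p-value, and the GC percent of each gene. Its headers name genotype, treatment, batch and genotype-by-treatment terms, so the authors' model held the batch. These headers were seen after the design had been fixed without a batch term, and the fit without the batch stayed the main one. Gene symbols, chromosomes and positions on GRCm38 were taken from the deposited table, and 3047 genes without a symbol keep their identifier.

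The test, its samples, the gene lists, the rule for named genes and the first set of other settings were chosen before the data were examined. Counts were normalized with TMM in edgeR 4.0.16 under R 4.3.3. Genes were kept with filterByExpr at a minimum count of 10 and a minimum total of 15, which left 17092 genes. All 18 libraries entered 1 fit with 1 mean per group, since 3 libraries give little information on the spread of a gene alone. Differences were tested with the robust quasi-likelihood F-test of edgeR, two-sided, with Benjamini-Hochberg adjustment within each of 13 contrasts, and a gene is called at an adjusted p under 0.05. The contrasts are 3 between media in WT, the same 3 in KO, KO against WT in each medium and over the average of the media, and 3 differences between the genotypes in the response to a medium (interactions). Fold changes are given as log2 with their standard error (SE), and levels as CPM, counts scaled to the effective library size by edgeR, mean ± SD. With 3 libraries against 3, an exact permutation test of a single gene cannot go below p = 0.1, so every call rests on the shared spread of the model. A gene with a count of 0 in all libraries of a group is given as a lower bound against a floor of 3 counts over that group.

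Gene lists were 25: Wnt/beta-catenin targets, ERK-responsive genes, EGF receptor family and ligands, Ras exchange factors, basal/myoepithelial markers, luminal markers, hormone-sensing luminal markers, luminal progenitor markers, milk and alveolar genes, mammary stem cell markers, proliferation genes, cholesterol synthesis genes, cornified envelope and squamous keratins, mesenchymal transcription factors and matrix, Notch pathway genes, interferon-stimulated genes, p53 targets, hypoxia and glycolysis genes, inflammatory chemokines and acute-phase genes, dissociation and heat-shock genes, and markers of fibroblasts, endothelial cells, lymphocytes, myeloid cells and adipocytes. They were written from general knowledge, not from these libraries, and some genes stand on more than 1 list. Each list was tested against the other genes with camera in limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over 325 tests. Camera with the correlation estimated from the data and fry were run as alternatives. Of 124 calls with the preset correlation, 9 held with the estimated one. These 9 stand in the results with both values. With the block and the estimated correlation 3 held, the milk genes in EGF against WR medium in WT and in EGF-WR against WR medium in both genotypes, and the other 6 were lost.

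Genes are named by 3 rules. In a contrast of 2 groups, these are the 8 largest changes up and the 8 down among called genes with at least 4 CPM on average and no overlap between the groups, leaving out predicted genes and genes without a symbol. From each called list, these are the 4 members with the smallest p. A fixed set of marker genes is given at least once. Called members that move against their list, and any other gene named outside these rules, were chosen after their values were seen.

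Batch numbers pair the libraries: after removing group means, the 45 pairs of libraries with the same number had correlations of 0.175 to 0.454, and the 90 pairs with different numbers had correlations of -0.285 to -0.00488. A fit with the batch as a block was chosen beforehand as a second setting, and its value stands beside a named gene, list or count where it changed the call or moved a count by more than 1.5 times. Other settings chosen beforehand were the RLE size factors, no low-count filter (30170 genes), a strict filter of 1 CPM in 9 libraries (13440 genes), the Wald test of DESeq2 1.42.0, a fit of only the 6 libraries compared, and leaving out each library. Leaving out a whole batch for gene counts, combining left-out libraries with the block, combining the block with an estimated correlation, and leaving out the genes near Rasgrp1 were chosen after seeing the data. Library totals spanned 24290097 to 31269899 counts, and the 10 most abundant genes held 4.31% to 6.20% of a library. Floors cover counting error only, and each SE and SD includes spread between libraries. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

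The tests were tried on simulated counts of 16657 genes for EGF against WR medium in WT, with 200 genes changed. The fit without the block recovered 56% of 2-fold and 90% of 4-fold changes, with 0 false calls among 146. The fit with the block recovered 82% and 98%, with 7 false calls among 187. DESeq2, run on 17092 genes, recovered 64% and 98%, with 3 false calls among 165. Overlap of transcripts was checked by shared stretches of 31 bases in the GENCODE annotation of GRCm38.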

Results

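RNA of mammary organoids was counted per gene in 18 libraries, 3 for each of 6 groups. The groups were wild-type (WT) and RasGRP1-deficient (KO) organoids in a medium with EGF, in a medium with a Wnt surrogate and R-spondin 2 (WR), or in a medium with all 3 factors (EGF-WR). Replicates 1, 2 and 3 of WT held 28894000, 28345745 and 28804993 counts in WR medium, 29682509, 29715771 and 31269899 in EGF medium, and 30475054, 30306883 and 27417474 in EGF-WR medium. Those of KO held 27397674, 25156341 and 29502663 counts in WR medium, 24290097, 25381986 and 29978161 in EGF medium, and 26964415, 28251241 and 30781440 in EGF-WR medium. Mitochondrial genes took 1.28% to 2.54% of a library, and 18926 to 22319 genes had a count. The first principal component held 19.4% of the variance, of which 56.9% lay between batches and 38.7% between media. The second held 17.3%, of which 79.5% lay between media. Over all tested genes the batch took 25.4% of the variance, the medium 29.9% and the genotype 4.75%.

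Rasgrp1, the gene for a Ras guanine nucleotide exchange factor, lies on chromosome 2 from 117279993 to 117343001 (GRCm38). It had 28, 10 and 25 counts in the 3 WT libraries in WR medium, 15, 15 and 21 in EGF medium, and 7, 6 and 18 in EGF-WR medium. In KO it had 0, 0 and 9 counts in WR medium, 0, 6 and 4 in EGF medium, and 0, 0 and 6 in EGF-WR medium. The sums were 145 counts in WT and 25 in KO, or 0.542 ± 0.254 CPM against 0.0988 ± 0.125 CPM (SD, n = 9 each). The difference over media was not called, with log2 -2.37 ± 0.77 SE and an edgeR adjusted p of 1. Expression was near the detection limit in WT, and which exons the allele lacks is not stated, so reads from a remaining part of the gene cannot be told from a low residual level. The related factor Rasgrp3 stood at 9.58 ± 3.86 CPM in WT and 10.6 ± 3.91 in KO (n = 9).

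EGF and WR media were compared first in WT, to ask how organoids driven by EGF receptor signals differ from organoids driven by Wnt signals, with respect to stem cell and lineage programs. Csn3, which encodes kappa-casein, reached 527 ± 82.0 CPM in EGF medium against 12.1 ± 5.51 in WR medium (SD, n = 3 each), 43.5-fold higher. Krt10, a suprabasal keratin of stratified epithelium, was lower, at 4.16 ± 0.856 CPM against 409 ± 272. Axin2, a feedback target of Wnt signalling, was 8.35-fold lower (log2 -3.06 ± 0.73 SE, adjusted p = 0.0214).

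Largest changes, here and below, are those among called genes with at least 4 CPM on average and no overlap between the groups. Among the largest increases in EGF medium were Bpifb5 (log2 5.80 ± 0.45), Bpifb1 (4.72 ± 0.87) and Lalba (4.60 ± 0.47), the last encoding alpha-lactalbumin. The others were Crispld2 (4.59 ± 0.36), Rtn1 (4.39 ± 0.46), the glutamine transporter Slc38a3 (4.34 ± 0.60) and the collagen IX gene Col9a1 (4.27 ± 0.44). The largest decreases were in genes of epidermal differentiation. Calm4 was 0 in all 3 EGF libraries and at least 601-fold lower, and the phospholipase gene Pla2g2f was also 0 and at least 311-fold lower. Krt1 fell by 10.35 ± 1.42 on the log2 scale, followed by the filaggrin gene Flg (-10.015 ± 2.07), Dsg1a (-8.63 ± 0.84), Krtdap (-7.84 ± 1.19) and Stfa3 (-7.37 ± 1.44). Stfa3 and Dsg1a have near-identical neighbours that can share reads. Of 20 measured cornified envelope and squamous keratin genes, 13 fell, 1 rose and 6 were not called over all genes, and 16 fell and 1 rose adjusted over the list alone. Their median log2 change was -4.13, and Krt6a (-2.95 ± 0.39) and Sbsn (-1.57 ± 0.16) were further examples, while Krt4 rose (1.22). The list was lower at a camera adjusted p of 8.51e-24, and adjusted p = 0.0587 with an estimated correlation.

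**Figure D1:**
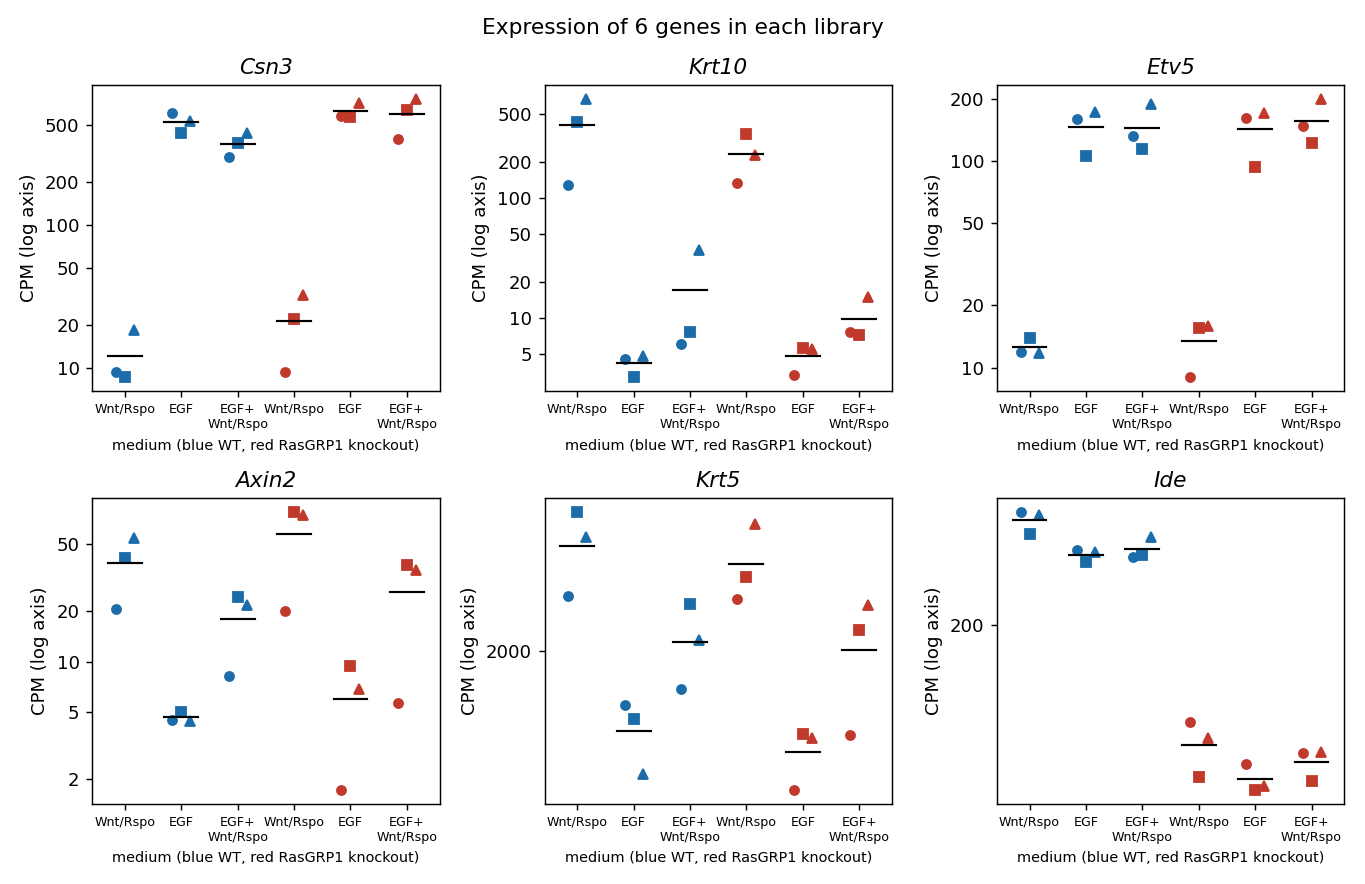
Level of 6 genes in each library in CPM on a log axis, with circles, squares and triangles for replicates 1, 2 and 3, blue for WT, red for KO and black lines for group means. Csn3 averages 12.1 CPM in WT in WR medium and 527 CPM in EGF medium, Krt10 averages 409 and 4.16 CPM, and Ide differs between the genotypes in every medium.

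Genes that respond to ERK, the kinase downstream of Ras, were higher in EGF medium. The ETS factor genes Etv1 (log2 3.81 ± 0.25), Etv5 (3.55 ± 0.30) and Etv4 (1.72 ± 0.30) rose, as did the ERK phosphatase gene Dusp6 (2.20 ± 0.57) and the pathway inhibitors Spred1 (0.90 ± 0.12) and Spry2 (0.98 ± 0.25). Of 25 measured ERK-responsive genes, 6 rose, 1 fell and 18 were not called, and 7 rose and 2 fell adjusted over the list alone. With the batch block 11 rose and 2 fell. The list was higher (camera adjusted p = 6.93e-08, and adjusted p = 0.324 with an estimated correlation). Spry4 was not called (0.70 ± 0.45, adjusted p = 0.561, and 0.0105 with the batch block). Cyclin D1 (Ccnd1), which stands on the ERK and the Wnt list, fell (-1.27 ± 0.17).

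Wnt targets were lower in EGF medium, which lacked the Wnt surrogate. Besides Axin2 and Ccnd1, the Wnt inhibitors Apcdd1 (-1.48 ± 0.25) and Wif1 (-1.46 ± 0.23) fell. Of 20 measured targets, 5 fell, 1 rose and 14 were not called, and 9 fell and 2 rose adjusted over the list alone. With the batch block 10 fell and 3 rose. The list was lower (camera adjusted p = 2.45e-04, 0.0493 with an estimated correlation, and 0.125 with both the estimate and the batch block), and Bambi rose against it (0.77). Lgr5, a stem cell receptor, was not called at -0.68 ± 0.28 (adjusted p = 0.227, and 0.00419 with the batch block). Its relative Lgr6 was at 0.33 ± 0.17 (0.377, and 0.0370 with the block) and the Wnt deacylase Notum at -1.77 ± 0.67 (0.177, and 0.0417 with the block).

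Luminal progenitor markers and milk genes were higher in EGF medium as lists. Of 17 measured luminal progenitor markers, 9 rose, 1 fell and 7 were not called, and 10 rose and 2 fell adjusted over the list alone. Examples were Hey1 (2.33 ± 0.22), Cd14 (1.62 ± 0.23) and the milk fat globule gene Mfge8 (1.57 ± 0.15), while Ehf fell (-0.97). The list was higher (camera adjusted p = 2.82e-15, 0.0347 with an estimated correlation, and 0.0897 with both). Of 15 measured milk and alveolar genes, 4 rose and 11 were not called, and 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 8.33e-09, 0.0347 with an estimated correlation, and 0.0182 with both). Csn1s1, an alpha-casein gene, rose (2.59 ± 0.54), while Csn2 was near the detection limit at 0.462 ± 0.141 and 0.0441 ± 0.0508 CPM. Of 14 measured hormone-sensing luminal markers, 4 rose, 1 fell and 9 were not called, and 6 rose and 1 fell adjusted over the list alone, with 8 and 1 under the block. The prolactin receptor gene Prlr (1.16 ± 0.15), Cited1 (2.31 ± 0.33), Stc2 (0.87 ± 0.20) and the EGF receptor ligand Areg (1.02 ± 0.28) rose, and Wnt4 fell (-1.22 ± 0.28). That list was higher (camera adjusted p = 1.82e-05, and adjusted p = 0.199 with an estimated correlation). The hormone receptor genes Esr1 (0.58 ± 0.26) and Pgr (0.54 ± 0.31) were called only with the batch block, at adjusted p = 0.0333 and 0.0134 against 0.304 and 0.493.

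Basal markers were lower. The keratins Krt5 (1415 ± 214 CPM in EGF medium against 3149 ± 568) and Krt14 (log2 -1.04 ± 0.24) fell, as did the basal factor Trp63 (-0.81 ± 0.15) and Igfbp2 (-1.33 ± 0.27). Of 20 measured basal markers, 5 fell and 15 were not called, and 6 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.00753, and adjusted p = 0.298 with an estimated correlation). The smooth muscle actin gene Acta2 was not called (0.23 ± 0.21), and neither were Krt8 (0.19 ± 0.22), Krt18 (0.32 ± 0.23), Elf5 (-0.13 ± 0.17), Kit (-0.17 ± 0.22) or Egfr (0.10 ± 0.14). Of 20 measured mammary stem cell markers, 3 rose, 4 fell and 13 were not called, and 4 rose and 4 fell adjusted over the list alone. Tspan8 rose (1.74 ± 0.29), Procr was at 0.07 ± 0.31, and the list was not called (camera adjusted p = 0.908). Its median log2 change was 0.15, its mean -0.20 and its test pointed down. Of 28 measured proliferation genes none was called, with Mki67 at -0.61 ± 0.23 (adjusted p = 0.176, and 0.0253 with the block), Mcm6 at -0.64 ± 0.23, Aurkb at -0.69 ± 0.26 and Hmgb2 at -0.81 ± 0.33. The last 3 were called with the block, at adjusted p = 4.73e-04, 0.00324 and 0.00609, against 0.156, 0.168 and 0.223 without it. With the batch block 12 proliferation genes fell and 1 rose. The list was lower (camera adjusted p = 2.54e-05, and adjusted p = 0.685 with an estimated correlation).

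Smaller shifts were seen in 4 other lists. Mesenchymal genes were higher (camera adjusted p = 0.00351, and adjusted p = 0.582 with an estimated correlation), with 1 of 16 risen, the cadherin gene Cdh2 (1.71 ± 0.32), and 5 with the block. Hypoxia and glycolysis genes were higher (0.00860, and adjusted p = 0.677 with an estimated correlation), with Hk1 (0.85 ± 0.15) and Egln3 (2.02 ± 0.50) the 2 of 20 that rose. Inflammatory genes were higher (0.00916, and adjusted p = 0.463 with an estimated correlation), with the chemokine Cxcl5 (2.79 ± 0.32) and Lcn2 (1.41 ± 0.20) the 2 of 21 that rose, and 4 with the block. Endothelial markers were higher (0.0108, and adjusted p = 0.582 with an estimated correlation), with Flt1 (1.75 ± 0.41) the 1 of 14 that rose, and 2 with the block. Counts adjusted over each list alone were the same for these 4 lists.

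Lists without a call in EGF against WR medium were the EGF receptor family (camera adjusted p = 0.163, 3 of 17 rose, and 5 rose and 1 fell with the block), Ras exchange factors (0.754), luminal markers (0.552), cholesterol synthesis genes (0.761), Notch pathway genes (0.516), interferon-stimulated genes (0.304), p53 targets (0.813), and dissociation and heat-shock genes (0.637). Of other cell types, fibroblast (0.904), lymphocyte (0.725), myeloid (0.517) and adipocyte markers (0.197) were not called. The median was positive and the test pointed down for lymphocyte (0.05), myeloid (0.17) and p53 genes (0.02), and the median was negative and the mean positive for Ras exchange factors (-0.003 and 0.04, test up).

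Between EGF and WR medium in WT, 543 genes were higher and 345 lower, 888 in all, at an edgeR adjusted p under 0.05. With the batch block 1457 were higher and 1182 lower, 2639 in all. Leaving out WT_EGF 3, WT_WR 3 or WT_WR 2 lowered the count to 500, 518 or 555, and leaving out batch 2 or 3 lowered it to 428 or 138. In 10 splits of the 6 libraries no other split gave a gene call, while another split called as many as 12 lists, or 10 if it parted every batch pair as the real one does.

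EGF-WR medium was then compared with WR medium in WT, to ask what EGF adds when Wnt signals are kept. Csn3 again rose, to 370 ± 70.02 CPM (log2 4.93 ± 0.42), and Etv5 rose to 145 ± 38.8 CPM against 12.5 ± 1.26 (n = 3). Krt10 fell to 16.9 ± 17.5 CPM (-4.61 ± 0.71) and Krt1 to 11.5 ± 15.7 CPM (-4.77 ± 1.02). Axin2, at 17.99 ± 8.60 CPM against 38.9 ± 17.0, was not called (-1.11 ± 0.68, adjusted p = 0.603).

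Other large increases were Bpifb5 (5.61 ± 0.45), the collagen gene Col2a1 (4.34 ± 0.88), Crispld2 (4.04 ± 0.35), Slc38a3 (3.88 ± 0.59), Chn2 (3.65 ± 0.28) and Col9a1 (3.48 ± 0.43). Other large decreases were Pla2g2f (-3.54 ± 0.66), the fibrillin gene Fbn2 (-3.40 ± 0.59), the epidermal caspase gene Casp14 (-3.39 ± 0.68), Dsc1 (-3.26 ± 0.57), Calm4 (-3.26 ± 0.79) and Adh7 (-3.06 ± 0.72). Of 20 cornified envelope genes 7 fell and 13 were not called, and 12 fell adjusted over the list alone, with Tgm3 at -5.69 ± 1.15 and a median of -1.96. That list was lower (camera adjusted p = 2.66e-11, and adjusted p = 0.204 with an estimated correlation).

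Of 25 ERK-responsive genes 5 rose and 20 were not called, with the same count adjusted over the list alone (camera adjusted p = 5.30e-07, and adjusted p = 0.356 with an estimated correlation). Etv1 (3.30 ± 0.24), Etv4 (1.74 ± 0.30) and Spred1 (0.66 ± 0.12) were among them, while Dusp6 was not called (1.53 ± 0.56, adjusted p = 0.213). Of 17 luminal progenitor markers 6 rose and 11 were not called, and 7 rose adjusted over the list alone, with Hey1 (1.98 ± 0.22), Lcn2 (1.06 ± 0.20) and Mfge8 (0.72 ± 0.15). That list was higher (camera adjusted p = 4.40e-11, 0.0493 with an estimated correlation, and 0.104 with both). Of 15 milk genes 4 rose and 11 were not called, and 5 rose adjusted over the list alone, with Lalba (4.07 ± 0.47) and Csn1s1 (2.83 ± 0.55). That list was higher (camera adjusted p = 5.57e-10, 0.0347 with an estimated correlation, and 0.0182 with both). Of 14 hormone-sensing markers 2 rose, Prlr (0.83 ± 0.15) and Cited1 (1.72 ± 0.33), and 12 were not called, among them Foxa1 (0.97 ± 0.27, adjusted p = 0.0794, and 0.00962 with the block) and Prom1 (0.97 ± 0.28, 0.0903, and 0.0199 with the block). Adjusted over the list alone 6 rose and 1 fell, and 5 rose with the batch block (camera adjusted p = 0.00293, and adjusted p = 0.356 with an estimated correlation).

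Of 20 basal markers none was called, 5 fell adjusted over the list alone, and 8 fell and 1 rose with the batch block. Trp63 (-0.58 ± 0.15), Krt5 (-0.60 ± 0.21), Krt14 (-0.67 ± 0.24) and Acta2 (-0.61 ± 0.21) were called only with the block, at adjusted p = 0.0129, 0.0333, 8.36e-04 and 0.0403, and Mylk was at -0.85 ± 0.28 (adjusted p = 0.142, and 0.00392 with the block). The basal list was lower (camera adjusted p = 0.0112, and adjusted p = 0.324 with an estimated correlation). Of 20 stem cell markers 2 fell and 18 were not called, and 5 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.0379, and adjusted p = 0.263 with an estimated correlation). The call was lost with the block (0.0656). The 2 that fell were Cdh5 (-1.34 ± 0.30), which is also an endothelial marker, and Nrp1 (-1.39 ± 0.35), while Tspan8 was at 1.06 ± 0.29 (adjusted p = 0.0701, and 0.00387 with the block) and Wnt10a at -0.97 ± 0.29 (0.0973, and 0.0233 with the block). Krt18 was at 0.57 ± 0.23 (adjusted p = 0.294, and 0.00866 with the block).

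Markers of other cell types were lower in EGF-WR than in WR medium. Of 14 endothelial markers 3 fell and 11 were not called, and 11 fell adjusted over the list alone and with the block (camera adjusted p = 3.01e-11, and adjusted p = 0.129 with an estimated correlation). Besides Cdh5 these were Pecam1 (-1.17 ± 0.28) and Tie1 (-1.39 ± 0.34). Of 16 fibroblast markers 2 fell, Gsn (-1.51 ± 0.32) and Dcn (-1.96 ± 0.48), 4 fell adjusted over the list alone and 9 with the block (camera adjusted p = 4.69e-07, and adjusted p = 0.356 with an estimated correlation). Of 12 adipocyte markers none was called, 12 fell adjusted over the list alone and 11 with the block, with a median of -2.48 (camera adjusted p = 5.05e-10, and adjusted p = 0.352 with an estimated correlation). Cidec was at -2.89 ± 0.92 (adjusted p = 0.134, and 8.36e-04 with the block) and Fabp4 at -2.46 ± 0.82 (0.162, and 0.00244 with the block). Of 14 myeloid markers none was called under any adjustment, with a median of -1.34 and Cd68 at -1.13 ± 0.44 (camera adjusted p = 1.83e-04, and adjusted p = 0.530 with an estimated correlation). Mesenchymal genes were lower beside them, with 2 of 16 fallen, Zeb2 (-1.72 ± 0.29) and Vim (-0.71 ± 0.14), the same count adjusted over the list alone, and 4 fallen and 1 risen with the block (camera adjusted p = 0.00124, and adjusted p = 0.568 with an estimated correlation).

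Hypoxia and glycolysis genes were higher in EGF-WR medium, with 5 of 20 risen and 7 adjusted over the list alone, among them Hk1 (0.90 ± 0.15), Egln3 (2.70 ± 0.51), the carbonic anhydrase gene Car9 (3.22 ± 0.75) and Eno1 (1.09 ± 0.26). That list was higher at a camera adjusted p of 5.57e-10, and adjusted p = 0.306 with an estimated correlation. Of 21 cholesterol synthesis genes none was called over all genes or over the list alone, and 17 rose with the batch block. Srebf2, a regulator of the pathway, was at 0.60 ± 0.20 (adjusted p = 0.153, and 1.99e-05 with the block) and Lss at 0.84 ± 0.32 (0.246, and 4.47e-04 with the block). The list was higher (camera adjusted p = 5.03e-08, and adjusted p = 0.533 with an estimated correlation). Of 24 interferon-stimulated genes none was called over all genes or over the list alone, and 6 rose with the block, with a median of 1.15 (camera adjusted p = 1.68e-08, and adjusted p = 0.530 with an estimated correlation). Rtp4 was at 1.38 ± 0.44 (adjusted p = 0.137, and 0.0241 with the block) and Irf7 at 1.97 ± 0.73 (0.222, and 0.0209 with the block). Wnt targets were not called (0.124), although Apcdd1 fell (-1.26).

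Between EGF-WR and WR medium in WT, 211 genes were higher and 193 lower, 404 in all, and with the batch block 841 were higher and 994 lower, 1835 in all. Leaving out WT_EGFWR 3, WT_WR 2, WT_WR 1, WT_EGFWR 1 or WT_WR 3 lowered the count to 130, 166, 175, 198 or 269, and leaving out a whole batch lowered it to between 59 and 113. DESeq2 called 858 genes, and the fit of only these 6 libraries called 216. No other of 10 splits gave a gene call, while another split called as many as 11 lists.

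EGF-WR medium was compared with EGF medium in WT, to ask what Wnt signals add to EGF. The keratin gene Krt79 was higher, at 152 ± 56.3 CPM against 24.01 ± 6.79, and the endothelial gene Pecam1 was lower, at 33.8 ± 13.4 CPM against 98.4 ± 8.84 (n = 3). Among the largest increases were Krt1 (log2 5.57 ± 1.32), Runx3 (3.05 ± 0.60), Aqp9 (2.70 ± 0.48), Krt79 (2.66 ± 0.45), Aqp3 (2.50 ± 0.56), Tmc5 (2.39 ± 0.33) and Dmkn (2.37 ± 0.39). Calm4 was at least 62.7-fold higher and Pla2g2f at least 26.2-fold higher, each against 0 counts in EGF medium. The largest decreases were Csmd1 (-3.44 ± 0.35), the chemokine Ccl11 (-2.65 ± 0.62), Abi3bp (-2.62 ± 0.52), Serpina3n (-2.58 ± 0.42), Sema3g (-2.45 ± 0.57), Masp1 (-2.40 ± 0.34), Tnxb (-2.36 ± 0.43) and Cpxm1 (-2.34 ± 0.35). Serpina3n belongs to a cluster of near-identical genes that can share reads.

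Of 20 Wnt targets 2 rose, Wif1 (1.68 ± 0.23) and Ccnd1 (0.81 ± 0.17), and 18 were not called, with 4 risen and 2 fallen adjusted over the list alone and 5 and 4 with the block. The list was higher (camera adjusted p = 0.0184, and adjusted p = 0.221 with an estimated correlation). Axin2 was called only with the block, at 1.95 ± 0.71 (adjusted p = 0.189, and 0.0125 with the block). Of 20 cornified envelope genes 5 rose and 15 were not called, and 8 rose and 1 fell adjusted over the list alone, with 9 and 1 under the block. Dsg1a (6.18 ± 0.82), Krtdap (5.99 ± 1.15), Krt6a (2.21 ± 0.38) and Sbsn (0.88 ± 0.15) were among them (camera adjusted p = 2.15e-09, and adjusted p = 0.263 with an estimated correlation). Of 28 proliferation genes none was called, 13 rose adjusted over the list alone and 20 with the block, with a median of 0.64 and Aurkb at 0.91 ± 0.26, Birc5 at 0.81 ± 0.28 and Mki67 at 0.62 ± 0.23. These 3 were called with the block, at adjusted p = 5.64e-04, 0.0191 and 0.0259, against 0.0816, 0.153 and 0.190 without it. The list was higher (camera adjusted p = 3.11e-11, and adjusted p = 0.510 with an estimated correlation).

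Of 14 endothelial markers 7 fell and 7 were not called, and all 14 fell adjusted over the list alone, among them Cdh5 (-1.64 ± 0.30), Pecam1 (-1.54 ± 0.28), Tie1 (-1.64 ± 0.34) and Esam (-1.21 ± 0.25). That list was lower (camera adjusted p = 9.54e-22, 0.0347 with an estimated correlation, and 0.104 with both). Of 16 fibroblast markers none was called, 6 fell adjusted over the list alone and 11 with the block, with a median of -1.31 (camera adjusted p = 3.55e-07, and adjusted p = 0.356 with an estimated correlation). Gsn was at -1.198 ± 0.31 (adjusted p = 0.0604, and 7.66e-04 with the block) and Col3a1 at -1.92 ± 0.55 (0.0854, and 0.00111 with the block). Of 12 adipocyte markers none was called over all genes or over the list alone, and 9 fell with the block, with a median of -1.82 (camera adjusted p = 4.47e-06, and adjusted p = 0.505 with an estimated correlation). Fabp4 was at -2.02 ± 0.81 (adjusted p = 0.236, and 0.004 with the block). Of 14 myeloid markers none was called, and 1 fell with the block, with a median of -1.48 and Lyz2 at -2.08 ± 0.89 (camera adjusted p = 0.0143, and adjusted p = 0.690 with an estimated correlation). Beside these, 2 of 16 mesenchymal genes fell, Zeb2 (-1.93 ± 0.29) and Vim (-0.92 ± 0.14), and 11 fell adjusted over the list alone and 13 with the block (camera adjusted p = 1.59e-11, and adjusted p = 0.204 with an estimated correlation). Inflammatory genes were lower, with 2 of 21 fallen, Cxcl5 (-2.21 ± 0.31) and Ccl2 (-1.47 ± 0.26), 5 fallen adjusted over the list alone, and 8 fallen and 1 risen with the block (camera adjusted p = 2.84e-04, and adjusted p = 0.306 with an estimated correlation).

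Cholesterol genes were higher (camera adjusted p = 2.05e-06, and adjusted p = 0.582 with an estimated correlation), with 1 of 21 risen over all genes and over the list alone, and 15 with the block. Interferon-stimulated genes were higher (5.13e-05, and adjusted p = 0.653 with an estimated correlation) with none of 24 called and Oas2 at 2.29 ± 1.02, and 2 rose with the block. Hypoxia genes were higher (0.00633, and adjusted p = 0.668 with an estimated correlation) with none of 20 called and Pdk1 at 1.04 ± 0.37 (adjusted p = 0.172, and 0.0112 with the block), and 2 rose with the block. Luminal markers were higher (0.0447, and adjusted p = 0.728 with an estimated correlation), with Ehf (0.65 ± 0.16) the 1 of 19 that rose, and 4 with the block. Notch genes were lower (0.0142, and adjusted p = 0.356 with an estimated correlation) with none of 16 called, 1 fallen adjusted over the list alone, 5 with the block and Notch4 at -1.27 ± 0.35 (adjusted p = 0.0761, and 0.0123 with the block). The calls of 2 other lists were lost with the block. Luminal progenitor markers were lower, with Aldh1a3 (-1.31 ± 0.17) and Mfge8 (-0.85 ± 0.15) fallen and Ehf risen among 17 (camera adjusted p = 0.0127, adjusted p = 0.475 with an estimated correlation, and 0.0817 with the block). With the block 7 of them fell and 4 rose. Ras exchange factors were lower, with Rasgrp3 (-1.05 ± 0.25) the 1 of 9 that fell (camera adjusted p = 0.0384, adjusted p = 0.263 with an estimated correlation, and 0.0533 with the block).

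Single markers called only with the block in EGF-WR against EGF medium in WT were Acta2 (-0.84 ± 0.21, adjusted p = 0.0505, and 0.00663 with the block), Areg (-0.95 ± 0.28, 0.0984 and 0.0393) and Egfr (-0.38 ± 0.14, 0.192 and 0.0151). Esr1 (-0.82 ± 0.26, 0.126 and 0.00512), Pgr (-0.78 ± 0.31, 0.236 and 8.63e-04), Tspan8 (-0.69 ± 0.29, 0.255 and 0.0189) and Spry4 (-0.87 ± 0.45, 0.384 and 0.00385) were likewise lower only with the block. Elf5 (0.40 ± 0.17, 0.269 and 0.0252), Krt5 (0.56 ± 0.21, 0.202 and 0.0476) and Krt14 (0.37 ± 0.24, 0.519 and 0.0432) were higher only with the block.

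Between EGF-WR and EGF medium in WT, 108 genes were higher and 261 lower, 369 in all, and with the batch block 1171 were higher and 1501 lower, 2672 in all. Each of the 6 libraries left out lowered the count, to between 52 (WT_EGF 3) and 218 (WT_EGFWR 1), and leaving out batch 2 or 3 lowered it to 37 or 0. DESeq2 called 946 genes. No other of 10 splits gave a gene call, while another split called as many as 11 lists.

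**Figure D2:**
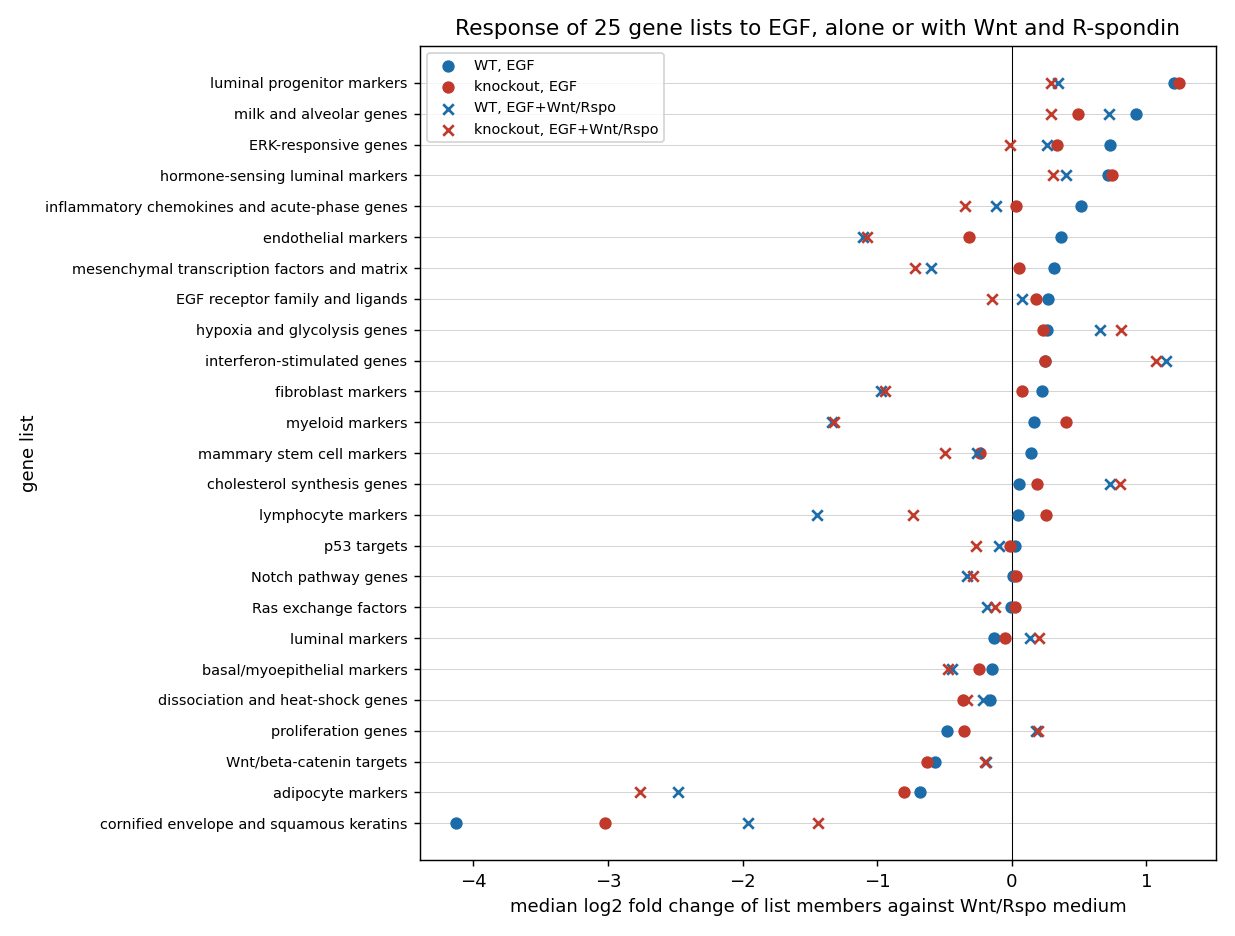
Median log2 fold change of each of 25 gene lists against WR medium, with dots for EGF medium and crosses for EGF-WR medium, blue for WT and red for KO. Cornified envelope genes lie at -4.13 in WT in EGF medium and at -1.96 in EGF-WR medium, and adipocyte markers lie at -2.48 in WT in EGF-WR medium.

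The same 3 comparisons were made in KO, to ask which responses to the media are present without RasGRP1. In EGF against WR medium, Csn3 was at 624 ± 81.2 CPM against 21.2 ± 11.5 and Krt10 at 4.78 ± 1.29 CPM against 234 ± 103 (n = 3). Bpifb5 (log2 5.56 ± 0.44), Rtn1 (5.14 ± 0.48), Lalba (4.18 ± 0.46), Slc38a3 (4.14 ± 0.59), Crispld2 (4.09 ± 0.35), Col9a1 (3.96 ± 0.43) and Col2a1 (3.68 ± 0.86) were among the largest increases, with Csn3 at 4.88 ± 0.42. Flg, with 0 counts in EGF medium, was at least 231-fold lower, and Calm4 (-8.79 ± 1.23), Krt1 (-8.71 ± 1.32), Krtdap (-7.213 ± 1.202), Sprr1b (-6.23 ± 1.48), Stfa3 (-6.16 ± 1.38), Dsg1a (-6.12 ± 0.73) and Krt10 (-5.61 ± 0.76) fell. Axin2 (-3.26 ± 0.74), Krt5 (-1.17 ± 0.21), Krt14 (-0.89 ± 0.24) and Trp63 (-1.06 ± 0.15) fell, and Etv5 (3.40 ± 0.30), Etv4 (1.88 ± 0.30) and Tspan8 (1.87 ± 0.29) rose. Mki67, Lgr5, Lgr6, Krt18, Esr1 and Pgr were called only with the block, at adjusted p = 0.0296, 0.0207, 0.00183, 0.0491, 0.0102 and 0.0159.

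In KO in EGF against WR medium, 8 of 17 luminal progenitor markers rose and 1 fell, and 10 rose and 2 fell adjusted over the list alone (camera adjusted p = 4.21e-13, 0.0347 with an estimated correlation, and 0.104 with both). Of 20 Wnt targets 6 fell and 1 rose, and 8 fell and 3 rose adjusted over the list alone (camera adjusted p = 2.54e-05, 0.0347 with an estimated correlation, and 0.0897 with both). Of 20 cornified envelope genes 11 fell and 1 rose, and 13 and 1 adjusted over the list alone (camera adjusted p = 3.51e-16, and adjusted p = 0.111 with an estimated correlation). Of 15 milk genes 3 rose, and 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 8.78e-06, and adjusted p = 0.111 with an estimated correlation). Of 25 ERK-responsive genes 4 rose and 1 fell, and 4 and 2 adjusted over the list alone (camera adjusted p = 0.00102, and adjusted p = 0.543 with an estimated correlation). Of 20 basal markers 4 fell, and 7 fell adjusted over the list alone, with 8 fallen and 1 risen under the block (camera adjusted p = 8.81e-05, and adjusted p = 0.118 with an estimated correlation). Of 14 hormone-sensing markers 3 rose, Prlr (1.06 ± 0.15), Cited1 (1.85 ± 0.33) and Stc2 (0.78 ± 0.20), and 7 rose and 2 fell adjusted over the list alone, with 8 and 1 under the block (camera adjusted p = 1.29e-05, and adjusted p = 0.171 with an estimated correlation). Proliferation genes were lower with none of 28 called over all genes or over the list alone, and 5 fallen and 1 risen with the block (camera adjusted p = 0.00325, and adjusted p = 0.802 with an estimated correlation). Hypoxia genes were higher with Hk1 (0.86 ± 0.15) the 1 of 20 that rose (camera adjusted p = 0.0358, adjusted p = 0.743 with an estimated correlation, and 0.0681 with the block). Mesenchymal genes were called only with the block (0.232, and 0.0332 with the block), and were not called with an estimated correlation (adjusted p = 0.895 with an estimated correlation, and 0.656 with both).

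In EGF-WR against WR medium in KO, Csn3 was at 601 ± 185 CPM (log2 4.83 ± 0.42) and Krt10 at 9.80 ± 4.30 CPM (-4.57 ± 0.72, n = 3). Bpifb5 (5.61 ± 0.44), Crispld2 (3.83 ± 0.34), Lalba (3.83 ± 0.46), Slc38a3 (3.65 ± 0.58), the muscarinic receptor gene Chrm3 (3.62 ± 0.33), Etv5 (3.54 ± 0.30) and Col2a1 (3.51 ± 0.85) rose most. Krt1 (-5.57 ± 1.07), Calm4 (-3.75 ± 0.82), Casp14 (-3.54 ± 0.69), Dsc1 (-3.41 ± 0.58), Fbn2 (-3.29 ± 0.59), Rnase1 (-3.14 ± 0.41) and Hcar1 (-3.09 ± 0.69) fell most. Etv1 (2.87 ± 0.24), Etv4 (1.74 ± 0.30) and Tspan8 (1.21 ± 0.29) rose, and Trp63 (-0.75 ± 0.15), Nrp1 (-1.53 ± 0.35) and Wnt10a (-1.24 ± 0.29) fell. Lists higher were luminal progenitor markers (6 of 17 rose, camera adjusted p = 7.59e-10, and adjusted p = 0.0635 with an estimated correlation) and milk genes (4 of 15, 4.02e-08, 0.0493 with an estimated correlation, and 0.0182 with both). Hypoxia genes (5 of 20 rose, 2.91e-11, adjusted p = 0.263 with an estimated correlation) and ERK-responsive genes (3 of 25, 0.00372, adjusted p = 0.582 with an estimated correlation) were higher too. The ERK list had a median of -0.01 and a mean of 0.19. Cholesterol genes (none of 21 called, 18 risen with the block, 3.87e-08, adjusted p = 0.533 with an estimated correlation) and interferon-stimulated genes (none of 24, 11 risen with the block, 4.64e-07, adjusted p = 0.563 with an estimated correlation) were higher. Adjusted over the list alone 7, 5, 13, 5, 2 and 0 genes rose on these 6 lists in the order given, and 1 ERK-responsive gene fell.

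Lists lower in EGF-WR against WR medium in KO were cornified envelope genes (4 of 20 fell, camera adjusted p = 2.33e-07, adjusted p = 0.329 with an estimated correlation) and basal markers (1 of 20, 5.61e-04, adjusted p = 0.171 with an estimated correlation). Stem cell markers were lower with 3 of 20 fallen and Tspan8 risen (0.00466, adjusted p = 0.124 with an estimated correlation). Mesenchymal genes (2 of 16 fell, 7.20e-05, adjusted p = 0.475 with an estimated correlation), fibroblast markers (3 of 16, 4.87e-06, adjusted p = 0.420 with an estimated correlation) and endothelial markers (4 of 14, 5.57e-10, adjusted p = 0.171 with an estimated correlation) were lower. Myeloid markers (none of 14, 0.00458, adjusted p = 0.621 with an estimated correlation) and adipocyte markers (none of 12, 1.84e-09, adjusted p = 0.356 with an estimated correlation) were lower. Adjusted over the list alone 7, 4, 6, 2, 3, 12, 0 and 12 genes fell on these 8 lists in the order given, and with the block 9, 8, 9, 6, 8, 11, 0 and 12 fell. Against these, 2 stem cell markers rose adjusted over the list alone, and with the block 3 of them and 1 basal marker rose. With the block luminal markers (camera adjusted p = 0.0659, and 0.0494 with the block) and proliferation genes (0.0517, and 0.0300) were called as higher. Neither was called otherwise, the luminal list having adjusted p = 0.743 with an estimated correlation and 0.750 with both, and the proliferation list having 0.895 and 0.807. Axin2 (-1.14 ± 0.67), Lgr5, Krt5, Krt14, Krt8, Krt18 and Acta2 were called only with the block, at adjusted p = 0.0469, 0.00879, 0.0423, 0.00121, 0.0467, 0.00709 and 0.01.

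In EGF-WR against EGF medium in KO, Krtdap (log2 5.89 ± 1.19) and Dsg1a (4.24 ± 0.71) had the larger increases among the cornified envelope genes, at under 4 CPM on average. Of genes above that level, BC100530 (log2 2.78 ± 0.61), Krt79 (2.54 ± 0.44), Aqp9 (2.51 ± 0.48), Dmkn (2.50 ± 0.39), Tmc5 (1.99 ± 0.33), Igfbp2 (1.99 ± 0.28), Dsc3 (1.97 ± 0.29) and Krt6a (1.90 ± 0.37) rose most. Csmd1 (-2.92 ± 0.34), Masp1 (-2.47 ± 0.34), Rtn1 (-2.35 ± 0.41), Cxcl14 (-2.24 ± 0.47), Serpina3n (-1.86 ± 0.41), Cxcl5 (-1.82 ± 0.30), Grik3 (-1.80 ± 0.34) and Ltbp2 (-1.78 ± 0.34) fell most. Wnt targets were higher (2 of 20 rose, Wif1 at 1.76 ± 0.23 and Ccnd1 at 0.80 ± 0.17, camera adjusted p = 0.00508, adjusted p = 0.131 with an estimated correlation), as were cornified envelope genes (3 of 20, 9.49e-07, adjusted p = 0.356 with an estimated correlation). Proliferation genes (none of 28 called, 14 risen with the block, 1.38e-09, adjusted p = 0.540 with an estimated correlation) and cholesterol genes (none of 21, 17 risen with the block, 1.31e-06, adjusted p = 0.582 with an estimated correlation) were higher. Interferon-stimulated genes (none of 24, 1.36e-05, adjusted p = 0.621 with an estimated correlation) and hypoxia genes (none of 20, 3.88e-06, adjusted p = 0.461 with an estimated correlation) were higher. Adjusted over the list alone 5, 4, 0, 1, 0 and 0 genes rose on these 6 lists in the order given, and with the block 5, 7, 14, 17, 0 and 4 rose. Against these, 2 Wnt targets and 1 cornified envelope gene fell adjusted over the list alone, and 3 and 1 with the block.

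Lower in EGF-WR against EGF medium in KO were mesenchymal genes (Zeb2 fell, 1 of 16, camera adjusted p = 6.35e-10, adjusted p = 0.263 with an estimated correlation) and inflammatory genes (Cxcl5 fell, 1 of 21, 0.0141, adjusted p = 0.475 with an estimated correlation). Of fibroblast (8.83e-06, adjusted p = 0.427 with an estimated correlation), endothelial (4.80e-08, adjusted p = 0.248 with an estimated correlation), myeloid (1.79e-05, adjusted p = 0.475 with an estimated correlation) and adipocyte markers (6.01e-07, adjusted p = 0.469 with an estimated correlation) no gene was called, and the lists were lower. The same held for hormone-sensing markers (0.00671, adjusted p = 0.399 with an estimated correlation) and Notch genes (0.0379, adjusted p = 0.461 with an estimated correlation). Adjusted over the list alone 6, 1, 4, 4, 0, 0, 2 and 0 genes fell on these 8 lists in the order given, and with the block 9, 3, 10, 8, 2, 8, 3 and 2 fell, while 1 hormone-sensing marker rose with the block. Luminal markers were called as higher only with the block (0.0765, and 0.0419 with the block), and had adjusted p = 0.743 with an estimated correlation and 0.736 with both. Axin2 (2.12 ± 0.71), Krt5, Elf5, Esr1, Pgr, Egfr, Spry4, Lgr6, Tspan8 and Acta2 were called only with the block, at adjusted p = 0.00698, 0.0281, 0.0282, 0.00275, 0.00199, 0.0286, 0.0123, 0.00626, 0.0300 and 0.0190.

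In KO, 438 genes were higher and 291 lower in EGF against WR medium, 729 in all, and 2306 with the batch block. In EGF-WR against WR medium 206 were higher and 233 lower, 439 in all, and 2179 with the block. In EGF-WR against EGF medium 44 were higher and 71 lower, 115 in all, and 1991 with the block. Leaving out KO_EGF 3 or KO_WR 3 lowered the first count to 437 or 469, leaving out KO_EGFWR 3, KO_WR 2, KO_WR 1 or KO_EGFWR 1 lowered the second to 167, 168, 175 or 219, and leaving out any library but KO_EGFWR 1 lowered the third to between 6 and 36. DESeq2 called 1121, 963 and 464 genes, and fits of only the 6 libraries compared called 363, 35 and 4. No other of 10 splits gave a gene call in any of the 3, while another split called as many as 12, 13 and 12 lists, or 8, 9 and 12 if it parted every batch pair.

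The responses of both genotypes to the media were set side by side, which share no library. Of the genes called in WT, 888 of 888, 403 of 404 and 368 of 369 had the same sign in KO for EGF against WR, EGF-WR against WR and EGF-WR against EGF medium. Both called 618, 294 and 104 genes, all with the same sign, where independent lists would share 19.8, 5.17 and 1.36 of the same sign. WT and KO shared the 3 batches, and libraries of the same number correlated. Those shared counts and the correlations below therefore hold any effect of the batch on the response to a medium. Over 11538 genes with at least 4 CPM the fold changes of WT and KO had Pearson's r of 0.923, 0.923 and 0.909 and Spearman's rho of 0.796, 0.789 and 0.848, across genes, which are not independent replicates. An interaction test asked whether RasGRP1 changes the response to a medium. EdgeR, DESeq2 and the fit with the block called 0 genes in all 3 comparisons. In the order above 121, 125 and 116 genes had an unadjusted edgeR p under 0.05, and 356, 286 and 306 with the block. Chance would give 855, so the test was conservative and 0 calls do not show equal responses. The deposited test table called 28 genes for EGF against WR and 36 for EGF-WR against EGF medium.

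Several lists passed the interaction test as lists with no single gene called. For EGF against WR medium the KO response was lower than the WT response in endothelial markers (camera adjusted p = 1.89e-11, median -0.71, and adjusted p = 0.129 with an estimated correlation) and ERK-responsive genes (3.31e-04, median -0.37, 0.766 without batch 2, and adjusted p = 0.530 with an estimated correlation). It was higher in cornified envelope genes (1.53e-06, median 0.73, and adjusted p = 0.356 with an estimated correlation). For EGF-WR against EGF medium the KO response was higher in endothelial markers (5.59e-13, median 0.66, and adjusted p = 0.111 with an estimated correlation). With the block, proliferation genes (0.0525, and 0.0162 with the block) and fibroblast markers (0.348, and 0.0279) were also called for EGF against WR medium, and fibroblast markers (0.159, and 0.0125) for EGF-WR against EGF medium. All 3 were lost with the estimate, the first at adjusted p = 0.895 with an estimated correlation and 0.802 with both. The fibroblast lists had 0.899 and 0.504 for EGF against WR medium, and 0.860 and 0.470 for EGF-WR against EGF medium.

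KO was compared with WT within each medium, to ask what the loss of RasGRP1 changes. The steadiest difference, of untested cause, was in Ide (insulin-degrading enzyme, chromosome 19), lower in KO in all media. It stood at 115 ± 5.84 CPM against 257 ± 6.21 in EGF medium (log2 -1.16 ± 0.09), 123 ± 7.18 against 262 ± 10.4 in EGF-WR medium (-1.10 ± 0.09) and 130 ± 12.8 against 291 ± 12.6 in WR medium (-1.16 ± 0.09, n = 3 each). In fits of only the 6 libraries compared Ide had adjusted p = 0.0387, 0.0572 and 0.148 in turn. Mapkbp1, a gene for a kinase-binding protein on chromosome 2, was higher in EGF (0.81 ± 0.12) and EGF-WR medium (0.76 ± 0.12). The mitochondrial creatine kinase gene Ckmt1 (1.23 ± 0.20) and Dynlt1b (1.08 ± 0.18) were higher in EGF medium. The remaining calls were Eif3j2, Pcna-ps2, Gm7658, Eif3j1 and an identifier without a symbol, each a member of a set of near-identical copies or of unknown position, and are uncertain. ENSMUSG00000116926 had 0 counts in WT and was at least 65.4-, 85.2- and 63.1-fold higher in KO in EGF, EGF-WR and WR medium.

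In all, 7 genes were higher and 1 lower in KO in EGF medium, 4 and 2 in EGF-WR medium, and 4 and 1 in WR medium. In this order 166, 190 and 227 genes had an unadjusted edgeR p under 0.05, again fewer than by chance. With the block 12, 14 and 14 were called, and DESeq2 called 14, 11 and 14. The fits of only the 6 libraries called 1, 0 and 0, and leaving out 1 library lowered the counts to 3 or 4 in EGF medium and to as few as 3 in both other media. None of the fixed markers was called, with Csn3 at 0.24 ± 0.36, Krt5 at -0.13 ± 0.21, Axin2 at 0.37 ± 0.71 and Etv5 at -0.04 ± 0.27 in EGF medium.

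Averaged over media, 16 genes were higher and 6 lower in KO, 22 in all, and 58 with the block, while DESeq2 called 41. Leaving out batch 2 or 3 lowered the count to 10 or 7. Ide fell from 270 ± 18.1 to 123 ± 10.3 CPM (SD, n = 9, adjusted p = 2.50e-09), and Wdfy1 (log2 -1.62 ± 0.19), Fgfbp3 (-1.47 ± 0.22) and Mfap1b (-0.78 ± 0.12) fell. Mapkbp1 (0.72 ± 0.07), Dynlt1b (1.01 ± 0.11), the myeloid receptor gene Sirpa (0.79 ± 0.10), Ckmt1 (0.84 ± 0.12), the protease inhibitor gene Spint1 (0.40 ± 0.06), Bloc1s6 (0.56 ± 0.09), Ppip5k1 (0.51 ± 0.08) and Tmem87a (0.43 ± 0.07) rose, as did Ehd4 (0.78 ± 0.14). Mfap1b and Dynlt1b have near-identical copies that can share reads. Of the 22 genes, 10 lay within 10 Mb of Rasgrp1 on chromosome 2, against 162 of 17092 tested genes (Fisher's exact test, p = 2.59e-15). They were Mapkbp1, Ckmt1, Spint1, Bloc1s6, Ppip5k1, Tmem87a and Ehd4, which rose, and Eif3j1, Mfap1b and Pla2g4b, which fell. Without the genes of this window 11 genes were called. Another 5 were copies of genes on chromosome 2 by shared sequence, Eif3j2 (4.56 ± 0.22) and Gm3650 (6.03 ± 0.97) of Eif3j1 (-2.89 ± 0.29), Pcna-ps2 (5.10 ± 0.45) of Pcna, Gm7658 (3.46 ± 0.32) of Eif3m and Gm6257 (5.49 ± 0.80) of Dnajc17. Pla2g4b (-6.41 ± 0.90) overlaps other genes, and Gm28438, with 0 counts in WT, was at least 51.4-fold higher.

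**Figure D3:**
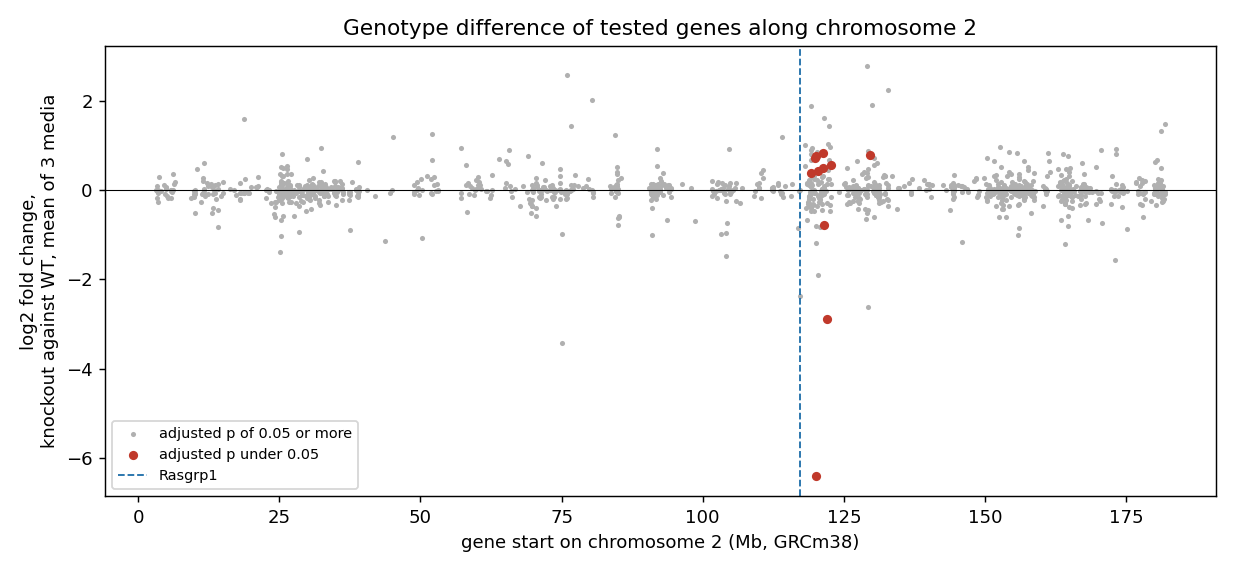
Log2 fold change of KO against WT averaged over media for tested genes on chromosome 2 by start position in Mb (GRCm38), with called genes in red and the position of Rasgrp1 as a dashed line. Of 22 called genes on all chromosomes, 10 lie within 10 Mb of the line.

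No member of any list was called between the genotypes, while several lists were called as lists. Averaged over media, interferon-stimulated genes were higher in KO with all 24 measured genes above 0, a median log2 of 0.85, and 13 risen adjusted over the list alone (camera adjusted p = 1.36e-22, and adjusted p = 0.248 with an estimated correlation). By batch their difference was 0.28, 0.32 and 1.63 in batches 1, 2 and 3. ERK-responsive genes (3.71e-04, median 0.19, 0.560 without batch 2, and adjusted p = 0.530 with an estimated correlation), the EGF receptor family (0.0293, and adjusted p = 0.523 with an estimated correlation) and luminal progenitor markers (0.0136, and adjusted p = 0.475 with an estimated correlation) were higher. Luminal markers (0.0253, and adjusted p = 0.678 with an estimated correlation), hypoxia genes (2.60e-04, and adjusted p = 0.552 with an estimated correlation) and inflammatory genes (0.00486, and adjusted p = 0.420 with an estimated correlation) were also higher. Proliferation genes (0.0485, and adjusted p = 0.895 with an estimated correlation) and myeloid markers (0.0163, and adjusted p = 0.698 with an estimated correlation) were lower. The myeloid difference was 0.238, -0.131 and -1.05 in batches 1, 2 and 3, and the list pointed up without batch 3 (0.935). None of these had a gene called adjusted over the list alone except the interferon list.

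Within single media, interferon-stimulated genes were higher in KO in EGF (camera adjusted p = 5.59e-13, and adjusted p = 0.381 with an estimated correlation), EGF-WR (1.92e-11, and 0.424) and WR medium (1.60e-12, and 0.398). In EGF medium luminal markers were higher (0.00722, and adjusted p = 0.614 with an estimated correlation), endothelial markers lower (1.31e-06, and 0.306), and cornified envelope genes higher (0.0127, and 0.644), the last lost with the block (0.0786). In EGF-WR medium luminal progenitor markers (0.0293, and adjusted p = 0.533 with an estimated correlation), hypoxia genes (7.56e-05, and 0.530), inflammatory genes (0.0366, and 0.548) and endothelial markers (1.02e-04, and 0.398) were higher, and myeloid markers lower (0.0441, and 0.743, lost with the block at 0.0807). With the block luminal markers (0.0770, and 0.0226 with the block) and proliferation genes (0.0760, and 0.0289) were called in EGF-WR medium. These 2 calls were lost too, the first at adjusted p = 0.743 with an estimated correlation and 0.680 with both, the second at 0.896 and 0.807. In WR medium ERK-responsive genes were higher (5.47e-07, and adjusted p = 0.356 with an estimated correlation), with Dusp6 at 174 ± 165 CPM in KO against 72.7 ± 16.4 in WT. That call rested on batch 2, without which the adjusted p was 0.371, and in that batch on the library KO_WR 2. Its Dusp6 stood at 360 CPM against 45.4 and 116 in the other 2 KO libraries, and Fosl1 at 95.2 against 2.51 and 10.7. Dissociation genes were high in the same library, with Atf3 at 380 CPM against 16.2 and 44.5, and Nr4a1 at 2280 against 115 and 210. The median ERK difference was -0.126, 0.928 and 0.265 in batches 1, 2 and 3, and that of the dissociation and heat-shock list -0.297, 0.571 and 0.246. An effect of genotype on ERK-responsive genes in WR medium was therefore not told apart from the state of this 1 library. In WR medium the EGF receptor family (0.0387, and 0.533), luminal progenitor markers (0.0145, and 0.475), mesenchymal genes (0.0239, and 0.695), hypoxia genes (0.0176, and 0.728), inflammatory genes (3.59e-05, and 0.248), heat-shock genes (0.0334, and 0.668) and endothelial markers (6.96e-04, and 0.475) were higher, the second value being the adjusted p with an estimated correlation. The heat-shock list pointed down without batch 2 (0.691). Proliferation genes (0.0165, and 0.880), cornified envelope genes (7.76e-04, and 0.533) and myeloid markers (9.27e-04, and 0.582) were lower there. Splits of the same libraries that mix the genotypes called as many as 13, 11 and 14 lists in EGF, EGF-WR and WR medium, against 4, 3 and 12 in the real split with adjustment within the comparison.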

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

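Of the tests below, the one of shared copies and all the splits had a prediction written before the result was seen, and all others were chosen only after it. List values are camera adjusted p-values for the difference between the KO and the WT response.

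For EGF against WR medium the responses differed in endothelial markers at 1.89e-11 and in cornified envelope genes at 1.53e-06. They differed in inflammatory genes at 2.35e-04, ERK-responsive genes at 3.31e-04, myeloid markers at 0.00385, mesenchymal genes at 0.00472 and milk genes at 0.00841. For EGF-WR against WR medium they differed in ERK-responsive genes at 0.00752 and in cornified envelope genes at 0.0259. For EGF-WR against EGF medium they differed in endothelial markers at 5.59e-13 and in cornified envelope genes at 0.0161. They differed there in milk genes at 0.0440 and in hypoxia genes at 0.0440. With an estimated correlation none of the 13 was called, the lowest adjusted p being 0.111, and with the batch block the last 3 named were lost, at 0.0871 for cornified envelope, 0.0754 for milk and 0.0533 for hypoxia genes.

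Genes called between the genotypes were weighed first. A strain segment carried with the targeted allele may explain part of them, since 10 of 22 called genes lay within 10 Mb of Rasgrp1. Reads shared between near-identical copies may explain others, since 3 of 12 called genes outside the window share transcript sequence with a gene in it, against 23 of 16912 other genes (Fisher's exact test, p = 7.02e-07). Loss of RasGRP1 acting on ERK-responsive genes was left open, with 0 called genes on the ERK or EGF receptor lists. Among genes of the window that were not called, 22.4% had an unadjusted p under 0.05 against 2.78% elsewhere.

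The higher interferon list in KO was weighed next. An excess in 1 batch may account for it, since the list difference was 1.63 in the highest batch against 0.28 and 0.32 in the others. RNA from immune cells stays open, with the myeloid list at -0.315 over all pairs but at 0.238, -0.131 and -1.05 in batches 1, 2 and 3, and the lymphocyte list at 0.305, -0.753 and -0.364. Both were thus lower in batches 2 and 3, and the interferon list lay above them by 1.29 and 1.74 standard errors over batches. The interferon list was higher in 8 of 9 pairs of libraries, and swaps of genotype within pairs gave as small a p in 7 of 100.

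The lower markers of other cell types in EGF-WR medium were weighed last. A smaller share of all non-epithelial cells is not likely, since the drops of 2 lists differed by 5.87 standard errors, with adipocyte markers at -2.29 ± 0.283 SE and endothelial markers at -1.05 ± 0.129 SE (6 genotype-by-batch sets). Over 3 batches the same difference was 4.12 standard errors. A smaller share of fibroblasts, endothelial and myeloid cells stays open, since the drops of these 3 lists differed by at most 1.52 standard errors over the 6 sets but by 2.00 over the 3 batches. The scaling of the libraries is not likely to be the whole cause, since 1 factor per library would lower every list alike and the adipocyte and endothelial lists parted.

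For gene calls between 2 groups, 10 splits are too few for a share under 0.05. The real split was the only 1 of 10 with as many calls in each of the 9 comparisons, and the highest other split had 0. For KO against WT over media the real split was the only 1 of 100 with as many as 22 genes, the highest other having 0. These 100 splits took the 9 pairs of libraries as independent. Pairs of 1 batch may not be, as in the interferon list, so shares of 100 may be too small. For the 3 interactions the real count was 0, which any split reaches, so the splits (100 of 100) say nothing about them.

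For list calls adjusted within a comparison, 10 splits are again too few for a share under 0.05. In WT the real split called 12, 15 and 16 lists for EGF against WR, EGF-WR against WR and EGF-WR against EGF medium. As many came from 2, 1 and 1 of 10 splits, the highest others having 12, 11 and 11. In KO the real split called 9, 17 and 16 lists for the same comparisons. As many came from 6, 1 and 1 of 10, the highest others having 12, 13 and 12. Between genotypes it called 4, 3 and 12 lists in EGF, EGF-WR and WR medium, as many as 8, 10 and 4 of 10, the highest others having 13, 11 and 14. Over media it called 8 lists, as many as 23 of 100, the highest other having 12. For the interactions of EGF against WR, EGF-WR against WR and EGF-WR against EGF medium it called 7, 0 and 1 lists, as many as 41, 100 and 95 of 100, the highest others having 14, 13 and 11. The value for the second of these is empty, since any split reaches 0. The batch numbers pair the libraries, and of the 9 other splits of 6 libraries 3 part every pair as the real one does, while 6 leave 2 pairs together. Among those 3 the highest list counts were 10, 11 and 8 in WT and 8, 9 and 12 in KO, each under the real count, and 9, 4 and 12 between genotypes, none under it. Mixed groups of libraries therefore gave as many list calls as the genotypes did.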

How the results depend on the processing

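The batch block was chosen beforehand, and its leave-out fits and the block with an estimated correlation were chosen only after the data were seen. For the genes and lists named in the text, the block changed no call other than those with its value beside them.

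With the batch block the counts for EGF against WR, EGF-WR against WR and EGF-WR against EGF medium were 2639, 1835 and 2672 in WT, and 2306, 2179 and 1991 in KO. It called 14 genes between the genotypes in EGF-WR medium, 14 in WR medium and 58 over media. DESeq2 called 858 and 946 genes in WT for EGF-WR against WR and against EGF medium. In KO it called 1121, 963 and 464 genes for the 3 comparisons in the same order. Between genotypes it called 14, 11 and 14 genes in EGF, EGF-WR and WR medium, and 41 over media. Fits of only the 6 libraries compared called 216 genes for EGF-WR against WR medium in WT, 363, 35 and 4 in KO, and 1, 0 and 0 between genotypes.

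With 1 library left out the count for EGF against WR medium was 500 to 698 in WT and 437 to 576 in KO. For EGF-WR against WR medium it was 130 to 352 in WT and 167 to 520 in KO. For EGF-WR against EGF medium it was 52 to 218 in WT and 6 to 107 in KO. Between genotypes it was 3 to 4 in EGF, 3 to 6 in EGF-WR and 3 to 5 in WR medium.

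With batch 1, 2 or 3 left out the counts for EGF against WR medium were 720, 428 and 138 in WT and 496, 334 and 103 in KO. For EGF-WR against WR medium they were 113, 112 and 59 in WT and 120, 126 and 85 in KO. For EGF-WR against EGF medium they were 315, 37 and 0 in WT and 115, 0 and 0 in KO. Between genotypes they were 2, 1 and 0 in EGF, 2, 2 and 0 in EGF-WR, and 3, 1 and 0 in WR medium, and 17, 10 and 7 over media.

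With the block and replicate 1, 2 or 3 of 1 group left out, the WT count for EGF against WR medium was 2062, 1979 and 1881 without a WR library and 2557, 2006 and 1693 without an EGF library. For EGF-WR against WR medium it was 1260, 1361 and 1295 without a WR and 1119, 1367 and 1180 without an EGF-WR library. For EGF-WR against EGF medium it was 2700, 1918 and 1191 without an EGF and 2053, 1569 and 1620 without an EGF-WR library. The KO count for EGF against WR medium was 1864, 2008 and 1688 without a WR library and 1904, 1573 and 1585 without an EGF library. For EGF-WR against WR medium it was 1451, 1586 and 1937 without a WR and 1463, 1725 and 1571 without an EGF-WR library. For EGF-WR against EGF medium it was 1362, 1316 and 922 without an EGF and 1472, 1344 and 978 without an EGF-WR library. Between genotypes the count was 9 to 12 in EGF, 9 to 12 in EGF-WR and 7 to 13 in WR medium. With the block and batch 1, 2 or 3 left out the counts for EGF against WR medium were 1916, 2107 and 969 in WT and 1523, 1774 and 906 in KO. For EGF-WR against WR medium they were 876, 1415 and 785 in WT and 945, 1637 and 1146 in KO. For EGF-WR against EGF medium they were 1954, 1819 and 653 in WT and 1060, 1313 and 366 in KO. Between genotypes they were 5, 10 and 5 in EGF, 10, 8 and 4 in EGF-WR, and 7, 7 and 3 in WR medium, and 90, 40 and 19 over media.

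Of 325 list tests 124 were called, 9 with an estimated correlation, 31 by fry, of which 27 were among the 124, and 3 with the block and an estimated correlation. Leaving out a batch reversed 2 lists. The heat-shock list between genotypes in WR medium turned down without batch 2, at 0.691, where the lowest adjusted p without a batch was 3.87e-04. The myeloid list over media turned up without batch 3, at 0.935, where the lowest was 3.23e-04. Of the list calls without 1 batch, 307 were kept and 63 lost. For ERK-responsive genes the calls between genotypes in WR medium, over media, and for both interactions were lost without batch 2, at 0.371, 0.560, 0.766 and 0.488.

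No setting reversed a call of a named gene, but many lost calls. Of 238 calls of named genes, 47 were lost with no low-count filter, 3 with RLE size factors and 1 with the strict filter, and none with DESeq2 or the block. In fits of only the 6 libraries compared 154 were kept and 72 lost. With 1 library or batch left out 1283 were kept and 787 lost, and with the block as well 1975 were kept and 95 lost.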

Other observations

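The table of tests in the deposited files, whose header carries batch terms, called more genes than the fits here. It called 3126, 2364 and 3325 genes in WT for EGF against WR, EGF-WR against WR and EGF-WR against EGF medium. It called 2816, 2694 and 2628 in KO, and 58, 135 and 131 between genotypes in EGF, EGF-WR and WR medium. Its interaction terms called the 36 and 28 genes given above, where the fits here called 0. Of the 2639 genes called here with the block for EGF against WR medium in WT, 2624 were shared with it.

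On chromosome 19, Fgfbp3 (-1.47 ± 0.22 SE) was lower in KO beside Ide, and Btaf1 (-0.39 ± 0.15) only with the batch block (adjusted p = 0.00132). Nearby Tnks2, Cpeb3, March5 and Kif11 (-0.17 to 0.12) were not called. A local cause was not tested.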
